A study of Mus musculus with 12 samples.

How the data were processed

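RNA from mouse skin was measured by bulk RNA sequencing in 12 libraries, 3 in each of 4 groups. The groups cross 2 genotypes, Foxp3 wild type (WT) and a Foxp3 form written DE2, with an irradiated and an untreated skin site. The sample labels write the altered genotype as Foxp3-E2, the protocol as Foxp3-DE2, and the series title as Foxp3dExon2. These were taken as 1 genotype. The irradiated site received 6 doses of ultraviolet B light (UVB). The sample labels give 200 mJ/cm2 and the protocol gives 100 mJ/cm2, and the difference could not be settled here. The irradiated patch was shaved, per the labels' protocols, and whether the untreated site was shaved is not given in the sources used here. No label ties a library to an animal, a batch or a day, so p-values measure the spread between libraries, some of which may share an animal. Within each genotype the untreated libraries carry the lower library numbers, so order of preparation, if the numbers follow it, cannot be separated from treatment.

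The deposited values are raw read counts per Ensembl gene, with no normalization. Per the submitters' processing notes, the genome build was GRCm38 and the tools were Trimmomatic 0.39, Picard 3.1.0, SAMtools 1.16 and HTSeq 2.0.2. The aligner, the annotation release, the strand setting and the handling of duplicate reads are not given in the sources used here. Without the strand setting, reads of genes that overlap on opposite strands cannot be told apart, and counts of near-identical copies, such as the Stfa, Sprr2, Krtap, Trim30 and Skint families, are uncertain. Each library held 53465 gene identifiers, of which 53274 were given a symbol from a GENCODE table of the same build. Gene positions are from that annotation, on GRCm38 and counted from 1.

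Total counts ranged from 2809142 to 4741726 per library. Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept with edgeR's filter on low counts over the 4 groups, which left 15126, and libraries were scaled with TMM factors. A quasi-likelihood model with robust estimation and 1 mean per group was fitted to all 12 libraries, which leaves 8 residual degrees of freedom, and 5 contrasts were tested: UVB in each genotype, genotype at each site, and the interaction of genotype and UVB. The common dispersion was 0.128, a biological coefficient of variation of 35.8%. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Log2 fold changes are given ± an approximate standard error worked back from the fit's test statistic. Levels are CPM, counts scaled to a common library total, ± SD with n = 3. CPM on the log2 scale used a prior count of 1. In 3 v 3 comparisons of a single value no permutation test can reach the threshold, so no such test was made.

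Fixed gene lists, 32 in number with 610 distinct genes, were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 lists of a comparison. An estimated correlation and the self-contained fry test were alternatives. Of the list genes, 4 had no match among the symbols. Bulk counts cannot tie a list member, such as Areg or Bcl11b, to the cell type its list names. Per comparison the text names the 6 higher and 6 lower genes with the largest change among those past the threshold, with a mean log2 CPM of at least 1 and, outside the interaction, all 3 libraries of one group above the 3 of the other. It also names 2 to 4 of the 4 members with the smallest p of each list that passed, and of the lists on T cells, interferons, cytotoxic cells, type 2 and IL-17 immunity whatever their p. A single gene within this rule was left out and is not reported here. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. A gene with no count in a group is given a bound from 3 counts over that group, and a gene with 1 to 3 counts a ratio with its exact 95% interval. Both cover counting error only. List medians were computed again with genes at 0 in a group set at that bound.

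The fit was tested on simulated counts drawn for each gene on its own from its mean over all libraries, with 50 genes changed at each fold. The changed genes were drawn from those with a mean log2 CPM of at least 1, so recovery among lower genes was not tested. At a 4-fold change it recovered 58% for UVB in WT (of 14619 genes in the fit), 70% for UVB in DE2 (14657), 60% for genotype with UVB (14620), 70% for genotype without UVB (14608) and 38% for the interaction (14580). At a 2-fold change the shares were 28%, 18%, 16%, 18% and 2%. The camera step called 0 of 50 unshifted lists in each simulated comparison, but simulated genes are independent of each other, so this does not test the preset correlation. Estimated correlations in the fixed lists ranged up to 0.808.

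Alternatives were RLE scaling, total counts with no composition factor, no filter, a stricter filter (at least 1 CPM in 3 libraries and 100 counts in all), only the libraries compared, a test against a 2-fold change, DESeq2 1.42.0, limma voom with sample quality weights, the mean log2 CPM of the skeletal muscle or the hair follicle list as a covariate, and each library left out in turn. A sex covariate was planned only if both sexes occurred. Ddx3y was at least 42.1 CPM and Xist at most 4.08 CPM in all 12 libraries, so it was not used. Replicate pairs differed by far more than counting noise, with a chi-square per degree of freedom of 9.43 to 48.4, and none was treated as a repeat deposit.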

Results

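Skin RNA was compared between mice with wild-type Foxp3 (WT) and mice with the DE2 form of Foxp3, the transcription factor that defines regulatory T cells. Skin came from a UVB-irradiated and an untreated site. The series title places the question in skin inflammation after UVB. Each of the 4 groups held 3 libraries. Total counts were 3852586 to 4392982 in untreated WT and 2915273 to 4212640 in irradiated WT libraries. They were 4205055 to 4741726 in untreated DE2 and 2809142 to 4062053 in irradiated DE2 libraries. Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245, plus strand) had 8 counts in irradiated DE2 libraries, 7 in replicate 2, 1 in replicate 1 and 0 in replicate 3, and 0 counts in the 9 libraries of the other groups. A group with 0 counts allows a level of up to 0.219 CPM in untreated WT, 0.273 CPM in irradiated WT and 0.267 CPM in untreated DE2. Foxp3 was below the filter and was not tested, and counts per gene cannot show whether exon 2 was present.

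The 3 untreated DE2 libraries lay apart from the other 9 on the first principal component, which held 39.7% of the variance. They were at 102 to 135, against -73.7 to -11.0. The skeletal muscle list took 12.1% ± 3.54 (SD, n = 3) of their counts. It took 4.67% ± 0.52 in untreated WT, 4.51% ± 3.04 in irradiated WT and 3.65% ± 0.37 in irradiated DE2. Keratin and keratin-associated genes took 1.33% ± 0.57 in untreated DE2 and 5.66% ± 0.96 in untreated WT. At the irradiated site they took 7.84% ± 1.53 in WT and 7.48% ± 0.64 in DE2. Irradiated WT replicate 2 had 7.84% of counts in the muscle list, against 3.81% and 1.89% in its group. Untreated DE2 replicate 1 had 8.08%, against 13.3% and 14.8%.

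**Figure D1:**
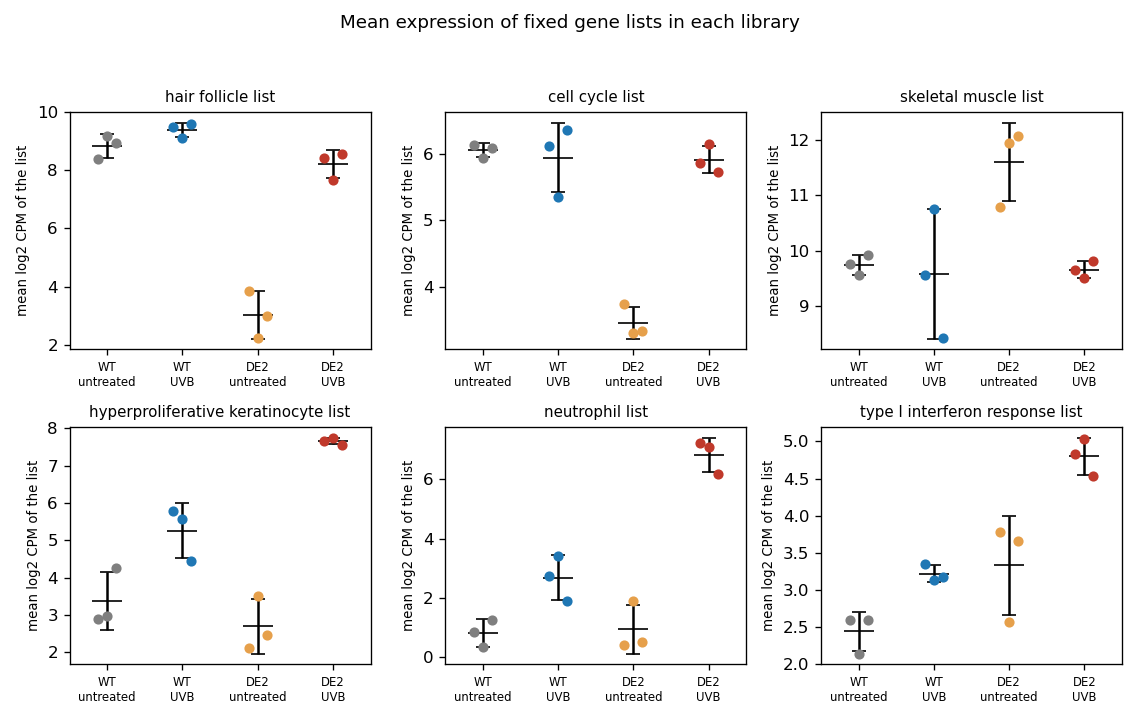
Mean log2 CPM of 6 fixed gene lists in each library (points), with the group mean and SD (black, n = 3), for WT and DE2 skin at untreated and UVB sites. The hair follicle score averaged 3.02 in untreated DE2 and 8.83 in untreated WT, and the neutrophil score 6.82 in irradiated DE2 and 2.68 in irradiated WT.

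In irradiated skin, transcripts of inflammation were higher in DE2 than in WT. Il1b, encoding the cytokine interleukin 1 beta (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139), was at 756 ± 437 CPM in DE2 and 10.7 ± 1.15 CPM in WT (SD, n = 3). Its log2 fold change was 6.13 ± 0.75 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0011). The neutrophil attractant Cxcl2 was higher by 6.94 ± 1.10 on the log2 scale, and the chemokine genes Ccl4 and Ccl3 by 5.96 ± 0.79 and 5.88 ± 0.76. Il33, an epithelial alarmin, was higher by 4.03 ± 0.39. Across 15126 genes, 448 passed, 356 higher and 92 lower in DE2. In all 448 the 3 libraries of a group lay beyond the 3 of the other, which held for 21.3% of all genes tested and holds for 10% by chance.

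Of 14 tested neutrophil genes, 9 were higher (14 adjusted over the list alone). Stfa2, a stefin gene, was higher by 3.42 ± 0.51 and the lectin receptor gene Clec4d by 6.27 ± 0.93. Camera placed the neutrophil list higher at an adjusted p of 9.19e-22, and at adjusted p = 0.0205 with an estimated correlation. Among 16 tested IL-17 and IL-36 genes 5 were higher (12 adjusted over the list alone). Il1b and Cxcl2 were among them, and S100a9, a subunit of calprotectin, was higher by 4.14 ± 0.83. By camera the IL-17 and IL-36 list was higher at an adjusted p of 3.85e-12, and had adjusted p = 0.0445 with an estimated correlation. The inflammatory chemokine list had 16 tested members, of which 7 were higher (10 adjusted over the list alone). Ccl4, Ccl3 and Cxcl2 were among them. The set tested higher in camera, with an adjusted p of 1.06e-10, and adjusted p = 0.0358 with an estimated correlation. Of 31 tested type I interferon genes, 9 were higher (20 adjusted over the list alone). Among these antiviral genes Rsad2 was higher by 2.96 ± 0.53, Zbp1 by 2.14 ± 0.40 and Bst2 by 1.58 ± 0.30. By camera the type I interferon list was higher at an adjusted p of 1.69e-17, and had adjusted p = 0.0369 with an estimated correlation. Among 21 tested interferon gamma genes 2 were higher (9 adjusted over the list alone). Those over all genes were Irf1, at 1.83 ± 0.34, and Cd274, encoding PD-L1, at 3.05 ± 0.71. The interferon gamma set tested higher in camera, with an adjusted p of 4.07e-07, and adjusted p = 0.199 with an estimated correlation.

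The hyperproliferative keratinocyte list had 20 tested members, of which 9 were higher (14 adjusted over the list alone). Krt6a, a keratin of wounded epidermis, was higher by 3.12 ± 0.46, Sprr2b, a cornified envelope gene, by 5.58 ± 0.68 and the growth factor gene Hbegf by 2.26 ± 0.37. Camera placed the list higher at an adjusted p of 2.03e-15, and at adjusted p = 0.0369 with an estimated correlation. Of 12 tested matrix protease genes, 5 were higher (7 adjusted over the list alone). Mmp13 was higher by 6.23 ± 1.15, Plaur by 5.22 ± 0.84 and Mmp9 by 2.80 ± 0.64. The matrix protease set tested higher in camera, with an adjusted p of 1.61e-09, and adjusted p = 0.0225 with an estimated correlation. Among 14 tested type 2 immunity genes 3 were higher, and 6 were higher and 1 was lower adjusted over the list alone. Those over all genes were Il33, Arg1, encoding an arginase, at 2.54 ± 0.34, and Il4ra, encoding a receptor chain shared by IL-4 and IL-13, at 1.93 ± 0.25. Camera placed the type 2 immunity list higher at an adjusted p of 4.17e-07, and at adjusted p = 0.0464 with an estimated correlation. The T cell list had 13 tested members, of which 3 were higher (4 adjusted over the list alone). Trbc2, a T cell receptor constant region gene, was higher by 1.66 ± 0.30 and Bcl11b, a T lineage factor, by 1.46 ± 0.26. By camera the T cell list was higher at an adjusted p of 1.43e-06, and had adjusted p = 0.0445 with an estimated correlation. Of 9 tested cytotoxic lymphocyte genes, 1 was higher (5 adjusted over the list alone). Nkg7 was higher by 3.60 ± 0.78, and Ctsw was at 2.76 ± 0.85. Camera placed the cytotoxic lymphocyte list higher at an adjusted p of 3.04e-06, and at adjusted p = 0.0479 with an estimated correlation. Among 15 tested immediate early genes 4 were higher (7 adjusted over the list alone). Ier3 was at 1.47 ± 0.25 and Dusp1 at 1.44 ± 0.31. By camera the immediate early list was higher at an adjusted p of 1.59e-05, and had adjusted p = 0.0369 with an estimated correlation. The regulatory T cell list did not pass. Of 6 regulatory T cell genes 1 was higher (1 adjusted over the list alone), while Ikzf2 and Tnfrsf18, which did not pass, were at -0.51 ± 0.41 and 0.36 ± 0.35, with a median of 0.26 and a camera adjusted p of 0.272 toward higher.

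Of 28 tested extracellular matrix genes, 8 were higher (18 adjusted over the list alone). Col5a1 was higher by 1.79 ± 0.30 and Tgfbi by 2.05 ± 0.35. By camera the extracellular matrix list was higher at an adjusted p of 2.36e-15, and had adjusted p = 0.0774 with an estimated correlation. Among 18 tested macrophage genes 2 were higher (2 adjusted over the list alone). Cd14, a receptor for bacterial lipopolysaccharide, was higher by 4.26 ± 0.47 and Ly6c2 by 4.13 ± 0.92. The macrophage set tested higher in camera, with an adjusted p of 1.50e-05, and adjusted p = 0.253 with an estimated correlation. The endothelial list had 14 tested members, of which 1 was higher (2 adjusted over the list alone). Emcn was higher by 2.39 ± 0.51, and Vwf was at 2.12 ± 0.56. Camera placed the endothelial list higher at an adjusted p of 1.38e-04, and at adjusted p = 0.238 with an estimated correlation. Of 14 tested complement genes, 1 was higher (1 adjusted over the list alone). C3 was higher by 1.14 ± 0.25, and C5ar1 was at 1.38 ± 0.54. The complement set tested higher in camera, with an adjusted p of 0.00449, and adjusted p = 0.454 with an estimated correlation. The complement call was lost without irradiated WT replicate 3, at adjusted p = 0.0626. Among 5 tested erythroid genes 0 passed, and 1 was higher adjusted over the list alone. The globin genes Hba-a1 and Hbb-bs were at 1.18 ± 0.34 and 1.02 ± 0.41. Camera placed the erythroid list higher at an adjusted p of 0.0043, and at adjusted p = 0.253 with an estimated correlation. The erythroid call was lost without irradiated WT replicate 3, at adjusted p = 0.0569. The Schwann cell list had 10 tested members, of which 0 passed (0 adjusted over the list alone). Pmp22 was at 0.81 ± 0.27 and Prx at 1.20 ± 0.43. By camera the Schwann cell list was higher at an adjusted p of 0.0246, and had adjusted p = 0.246 with an estimated correlation. The Schwann cell call was lost without irradiated WT replicate 2 or irradiated DE2 replicate 1, at adjusted p = 0.182 and 0.0765. The Schwann cell list had adjusted p = 0.0513 with only the libraries compared and 0.193 without both irradiated WT replicate 2 and untreated DE2 replicate 1. Of 31 tested hair follicle genes, 4 were lower (24 adjusted over the list alone). Lef1 was at -1.38 ± 0.32 and Foxn1 at -1.18 ± 0.28. Camera placed the hair follicle list lower at an adjusted p of 1.74e-17, and at adjusted p = 0.0873 with an estimated correlation. Among 12 tested melanocyte genes 2 were lower (8 adjusted over the list alone). Those over all genes were Dct and Tyr, encoding tyrosinase, at -1.39 ± 0.32, and Mlana was at -1.07 ± 0.28. By camera the melanocyte list was lower at an adjusted p of 4.17e-07, and had adjusted p = 0.0774 with an estimated correlation.

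The largest rises were in genes near 0 counts in irradiated WT. Osm, encoding the cytokine oncostatin M (ENSMUSG00000058755, chromosome 11, 4236420 to 4241026), had 1201 counts in DE2 and 1 in WT. Its ratio was 1253, with a 95% counting interval of 224 to 49514. With 0 counts in WT, P4ha3 was at least 55.3-fold higher in DE2, Mcemp1 at least 46.6-fold and Trim30b at least 35.8-fold. Likewise Kcns3 was at least 29.2-fold higher and the T cell costimulator gene Icos at least 24-fold. Kcnj16 had 0 counts in DE2 and was at least 11.8-fold lower. The ratio of DE2 to WT was 0.0222 for Zfp286 (interval 5.50e-04 to 0.13) and 0.0267 for Ppp2r2c (6.60e-04 to 0.158). It was 0.0394 for Col4a6 (0.00465 to 0.149) and 0.0464 for Dab1 (0.00545 to 0.177), and Skint5 had a log2 fold change of -3.65 ± 0.74. Without irradiated WT replicate 1 or 3 the count of 448 was 213 or 171, and without irradiated DE2 replicate 1, 2 or 3 it was 212, 130 or 267. It was 49 against a 2-fold change, 87 with the hair follicle covariate, 754 without both irradiated WT replicate 2 and untreated DE2 replicate 1, 806 with limma voom, 853 with DESeq2 and 1031 without a filter. With the hair follicle covariate 0 of 14 neutrophil genes passed. With an estimated correlation and the muscle covariate, the T cell and type 2 immunity lists no longer passed, at adjusted p = 0.0687 and 0.0693. With an estimated correlation and the hair follicle covariate, none of the 10 lists that had passed with an estimated correlation did, the lowest adjusted p being 0.0785 and that of the T cell list 0.128. At the preset correlation the hair follicle covariate ended the calls of the hair follicle, melanocyte, endothelial and Schwann cell lists, at adjusted p = 0.883, 0.28, 0.0883 and 0.0742. The hair follicle call was bound to end, as that list made the covariate.

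**Figure D2:**
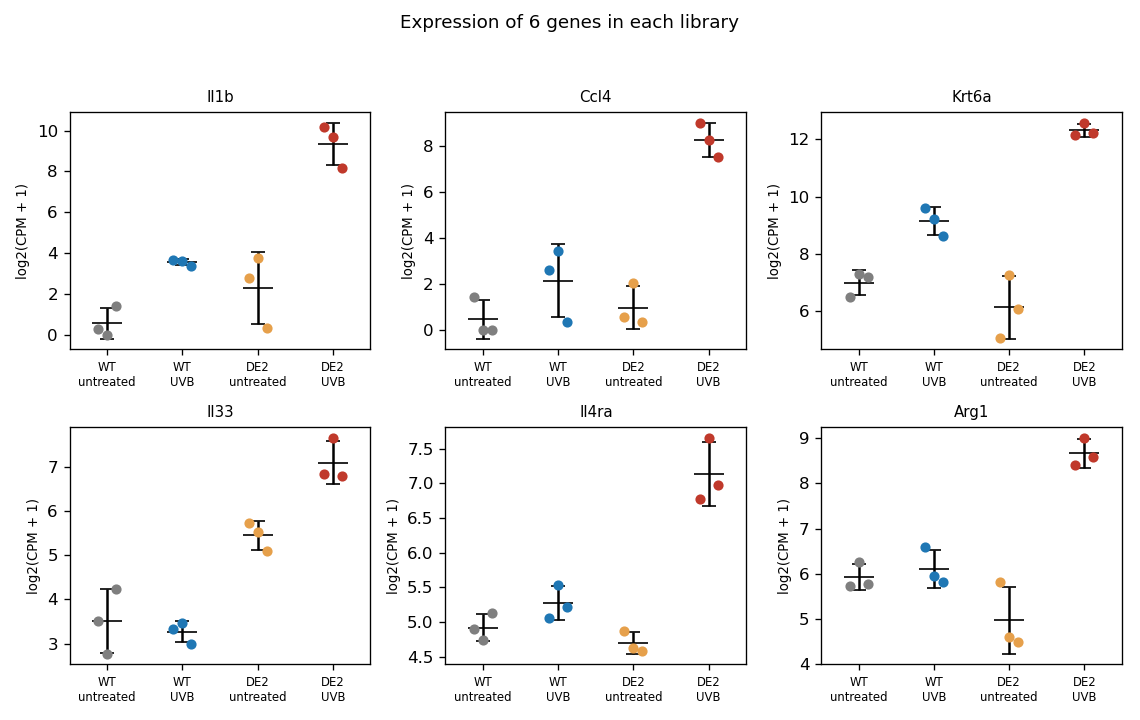
Expression of 6 genes as log2(CPM + 1) in each library (points), with the group mean and SD (black, n = 3), for WT and DE2 skin at untreated and UVB sites. All 6 passed the test between irradiated DE2 and irradiated WT, with log2 fold changes from 1.93 for Il4ra to 6.13 for Il1b.

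At the untreated site, genes of hair formation, pigment and cell division were lower in DE2 than in WT. Krt73, a keratin of the inner root sheath (ENSMUSG00000063661, chromosome 15, 101793308 to 101802346), was at 966 ± 316 CPM in WT and 14.1 ± 7.82 CPM in DE2 (SD, n = 3). Its log2 fold change was -6.09 ± 0.40 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 3.28e-07). The hair follicle list had 31 tested members, of which 31 were lower (31 adjusted over the list alone). Lef1, a factor of hair matrix cells, was at -6.64 ± 0.46, and Krtap16-1 at -6.94 ± 0.45. The hair follicle median was -6.02 (log2), and -5.93 with members at 0 counts at their bound. The hair follicle set tested lower in camera, with an adjusted p of 2.21e-75, and adjusted p = 0.0138 with an estimated correlation. Of 12 tested melanocyte genes, 10 were lower (11 adjusted over the list alone). Dct and Mlana were at -5.61 ± 0.31 and -7.11 ± 0.43. The melanocyte median was -6.16 (log2), and -5.62 with members at 0 counts at their bound. By camera the melanocyte list was lower at an adjusted p of 2.09e-28, and had adjusted p = 0.0138 with an estimated correlation. Among 26 tested cell cycle genes 25 were lower (26 adjusted over the list alone). Top2a and Ube2c were at -2.86 ± 0.27 and -2.95 ± 0.25. The cell cycle set tested lower in camera, with an adjusted p of 6.79e-28, and adjusted p = 0.079 with an estimated correlation. In all, 3477 genes passed, 1782 higher and 1695 lower in DE2.

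The muscle share was 12.1% ± 3.54 in untreated DE2 and 4.67% ± 0.52 in untreated WT. The skeletal muscle list had 23 tested members, of which 20 were higher (23 adjusted over the list alone). Myh2 was higher by 3.06 ± 0.45 and Mb, encoding myoglobin, by 2.36 ± 0.43. Camera placed the skeletal muscle list higher at an adjusted p of 4.77e-10, and at adjusted p = 0.731 with an estimated correlation. Of 15 tested circadian clock genes, 7 were higher (7 adjusted over the list alone). Nr1d1 was higher by 1.91 ± 0.34 and Dbp by 1.60 ± 0.28. The circadian clock set tested higher in camera, with an adjusted p of 7.11e-04, and adjusted p = 0.296 with an estimated correlation. Among 17 tested adipocyte genes 6 were higher (6 adjusted over the list alone). The lipase genes Pnpla2 and Lpl were higher by 1.85 ± 0.26 and 1.47 ± 0.26. Camera placed the adipocyte list higher at an adjusted p of 0.00619, and at adjusted p = 0.748 with an estimated correlation. The adipocyte call was lost without untreated DE2 replicate 3, at adjusted p = 0.121. The interferon gamma list had 21 tested members, of which 11 were higher (14 adjusted over the list alone). The GTPase genes Iigp1 and Igtp were higher by 2.99 ± 0.70 and 2.43 ± 0.59. By camera the interferon gamma list was higher at an adjusted p of 2.87e-04, and had adjusted p = 0.731 with an estimated correlation. Of 31 tested type I interferon genes, 10 were higher (11 adjusted over the list alone). Parp14 was higher by 2.42 ± 0.41 and Ifit1 by 2.44 ± 0.59. Camera placed the type I interferon list higher at an adjusted p of 7.52e-04, and at adjusted p = 0.731 with an estimated correlation. Among 14 tested complement genes 4 were higher (4 adjusted over the list alone). C3 was higher by 1.26 ± 0.25 and Serping1 by 1.36 ± 0.36. By camera the complement list was higher at an adjusted p of 0.0135, and had adjusted p = 0.748 with an estimated correlation. The complement call was lost without untreated WT replicate 3 or untreated DE2 replicate 1, at adjusted p = 0.093 and 0.173. The erythroid list had 5 tested members, of which 2 were higher (4 adjusted over the list alone). Hba-a1 was higher by 1.21 ± 0.34 and Hbb-bs by 1.30 ± 0.41. The erythroid set tested higher in camera, with an adjusted p of 0.0381, and adjusted p = 0.748 with an estimated correlation. The erythroid call was lost without untreated WT replicate 1, irradiated WT replicate 2 or untreated DE2 replicate 1, at adjusted p = 0.0648, 0.0603 and 0.0939. Without both irradiated WT replicate 2 and untreated DE2 replicate 1, the type I interferon, interferon gamma, complement and erythroid calls were lost, at adjusted p = 0.0904, 0.0631, 0.267 and 0.187. Of 14 neutrophil genes 0 passed, and the list had a camera adjusted p of 0.542.

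The lists for T cells, regulatory T cells, cytotoxic cells, type 2 immunity and the IL-17 and IL-36 axis did not pass in untreated skin. Of 13 T cell genes 2 were higher (1 adjusted over the list alone), while Bcl11b was at 1.11 ± 0.25 and Cd27 at 2.28 ± 0.75, with a median of 0.74 and a camera adjusted p of 0.213 toward higher. The T cell list passed without a filter (adjusted p = 0.0336). Of 6 regulatory T cell genes 1 was lower (1 adjusted over the list alone), while Areg was at -1.63 ± 0.50 and Tnfrsf18, which did not pass, at 0.88 ± 0.34, with a median of 0.67 and a camera adjusted p of 0.499 toward higher. Of 9 cytotoxic lymphocyte genes 0 passed (0 adjusted over the list alone), with a median of 0.93 and a camera adjusted p of 0.519 toward higher. Among them Klrd1 had 1 count in DE2 and 19 in WT, a ratio of 0.0641 (interval 0.00154 to 0.403), and Gzma had 10 and 0, at least 4.06-fold higher. Of 14 type 2 immunity genes 1 was higher (1 adjusted over the list alone), while Il33 was at 1.93 ± 0.36 and Arg1, which did not pass, at -0.84 ± 0.34, with a median of -0.11 and a camera adjusted p of 0.716 toward higher. Of 16 IL-17 and IL-36 genes 2 were higher (1 adjusted over the list alone), while Il1b was at 3.18 ± 1.05 and S100a9, which did not pass, at 1.68 ± 0.85, with a median of 0.56 and a camera adjusted p of 0.209 toward higher. The IL-17 and IL-36 list passed without untreated WT replicate 3 (adjusted p = 0.0245). With 0 counts in untreated DE2, Krtap24-1 was at least 528-fold lower, Tyr at least 223-fold and Krtap5-3 at least 130.0-fold. Dlx4, Sptssb and Oca2 were lower by at least 122-fold, 107-fold and 89-fold. Pnmt and Fgf9 had 0 counts in untreated WT and were at least 29.6-fold and 23.9-fold higher. The ratio of DE2 to WT was 69.4 for Cyp1a1 (interval 12 to 2789) and 25.6 for Pgf (4.11 to 1058). Tnni3k and Clec4b1 were higher by 4.35 ± 1.12 and 3.77 ± 1.18. With total counts in place of TMM the median of all genes moved from 0.03 to -0.37, and the higher share of calls from 51.3% of 3477 to 20.7% of 3799. The count was 454 with the muscle covariate, 777 against a 2-fold change and 2108 without untreated WT replicate 2. It was 0 with the hair follicle covariate in edgeR, with 708 genes at an unadjusted p under 0.05. DESeq2 and limma voom, run without a covariate, called 4071 and 4603. At the preset correlation the hair follicle covariate turned the muscle list lower, with a median of -1.79 and adjusted p = 0.0204. It ended the calls of the hair follicle, adipocyte and clock lists, at adjusted p = 0.695, 0.498 and 0.915. The muscle covariate ended those of the muscle list, at adjusted p = 0.887, and of the adipocyte and erythroid lists, both at 0.34. With an estimated correlation and the hair follicle covariate, the hair follicle and melanocyte lists had adjusted p = 0.768 and 0.526.

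In WT skin 3 genes differed between the sites, all higher at the irradiated site. Klk6, a kallikrein protease gene (ENSMUSG00000050063, chromosome 7, 43824499 to 43832030), rose from 52 ± 23.6 to 318 ± 143 CPM (SD, n = 3). Its log2 fold change was 2.61 ± 0.36 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0261). Rbp2, a retinol-binding protein gene (ENSMUSG00000032454, chromosome 9, 98486115 to 98509781), rose by 2.08 ± 0.30. Flg, encoding the barrier protein filaggrin (ENSMUSG00000102439, chromosome 3, 93273523 to 93293686), rose by 1.96 ± 0.28. Among the 15126 genes, 689 had an unadjusted p under 0.05.

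The hyperproliferative keratinocyte list had 20 tested members, of which 0 passed, and 13 rose adjusted over the list alone. Krt6a was at 2.18 ± 0.44 and Krt16 at 3.23 ± 0.66. The list median was 2.04 (log2), and 1.63 with members at 0 counts at their bound. By camera this list was higher at an adjusted p of 3.27e-23, and had adjusted p = 0.0391 with an estimated correlation. Of 14 tested neutrophil genes, 0 passed, and 7 rose adjusted over the list alone. Stfa3 was at 3.20 ± 0.52 and Stfa2 at 2.61 ± 0.59. The neutrophil median was 3.27 (log2), and 1.82 with members at 0 counts at their bound. It was 2.15 without irradiated WT replicate 1. Camera placed the neutrophil list higher at an adjusted p of 1.90e-15, and at adjusted p = 0.0391 with an estimated correlation. Among 31 tested type I interferon genes 0 passed, and 4 rose adjusted over the list alone. Bst2 was at 1.51 ± 0.31 and Isg15 at 2.09 ± 0.49. By camera the type I interferon list was higher at an adjusted p of 1.20e-11, and had adjusted p = 0.171 with an estimated correlation. The epidermal differentiation list had 40 tested members, of which 1 rose, and 11 rose and 1 fell adjusted over the list alone. Beside Flg, Lce3c was at 2.04 ± 0.40. The epidermal differentiation set tested higher in camera, with an adjusted p of 2.25e-11, and adjusted p = 0.374 with an estimated correlation. Of 18 tested macrophage genes, 0 passed, and 2 rose adjusted over the list alone. Cd14 was at 1.90 ± 0.51 and Fcgr1 at 3.22 ± 0.67. By camera the macrophage list was higher at an adjusted p of 1.52e-09, and had adjusted p = 0.321 with an estimated correlation. Among 16 tested IL-17 and IL-36 genes 0 passed, and 4 rose adjusted over the list alone. S100a9 and Il1b were at 4.03 ± 0.87 and 3.98 ± 0.99. The IL-17 and IL-36 set tested higher in camera, with an adjusted p of 1.07e-07, and adjusted p = 0.291 with an estimated correlation. The hair follicle list had 31 tested members, of which 0 passed (0 adjusted over the list alone). The hair genes Krt86 and Krtap3-2 were at 0.97 ± 0.38 and 0.94 ± 0.37. Camera placed the hair follicle list higher at an adjusted p of 1.08e-08, and at adjusted p = 0.521 with an estimated correlation. Of 14 tested complement genes, 0 passed (0 adjusted over the list alone). C1s1 was at 0.85 ± 0.30 and C1ra at 1.29 ± 0.44. The complement set tested higher in camera, with an adjusted p of 2.19e-05, and adjusted p = 0.521 with an estimated correlation. The complement call was lost without untreated WT replicate 3, at adjusted p = 0.0685. Among 21 tested interferon gamma genes 0 passed (0 adjusted over the list alone). Iigp1 was at 1.95 ± 0.69 and Gbp3 at 1.94 ± 0.68. Camera placed the interferon gamma list higher at an adjusted p of 0.00261, and at adjusted p = 0.676 with an estimated correlation. That call was lost without irradiated WT replicate 2 (adjusted p = 0.0655), and without both it and untreated DE2 replicate 1 (0.0886). The adipocyte list had 17 tested members, of which 0 passed (0 adjusted over the list alone). Adipoq was at -0.87 ± 0.56 and Pck1 at -1.35 ± 0.55. By camera the adipocyte list was lower at an adjusted p of 7.67e-04, and had adjusted p = 0.676 with an estimated correlation. The adipocyte call was lost without untreated WT replicate 3 or irradiated WT replicate 3, at adjusted p = 0.164 and 0.0553. The lists for T cells, regulatory T cells, cytotoxic cells and type 2 immunity did not pass. Of 13 T cell genes 0 passed (0 adjusted over the list alone), while Cd5 was at 2.61 ± 1.20, Cd27 at 1.06 ± 0.75 and Cd3g at -0.96 ± 0.80, with a median of -0.18 (-0.10 with bounds for members at 0 counts) and a camera adjusted p of 0.508 toward lower. Of 6 regulatory T cell genes 0 passed (0 adjusted over the list alone), while Tnfrsf4 was at -0.93 ± 0.38 and Ikzf2 at -0.83 ± 0.40, with a median of -0.47 (-0.11 with bounds for members at 0 counts) and a camera adjusted p of 0.377 toward lower. Of 9 cytotoxic lymphocyte genes 0 passed (0 adjusted over the list alone), while Nkg7 was at -1.72 ± 0.76 and Ctsw at -1.27 ± 0.85, with a median of -0.04 (0.00 with bounds for members at 0 counts) and a camera adjusted p of 0.619 toward lower. Of 14 type 2 immunity genes 0 passed (0 adjusted over the list alone), while Il4ra was at 0.37 ± 0.25 and Ccr4 at -1.34 ± 0.75, with a median of 0.26 and a camera adjusted p of 0.642 toward lower.

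The count of 3 genes for UVB in WT was 0 with only the WT libraries, against a 2-fold change and with the hair follicle covariate. It was also 0 without untreated WT replicate 1 or 2, irradiated WT replicate 1 or any 1 irradiated DE2 library, and 1 without untreated WT replicate 3 or with total counts. It was 5 without untreated DE2 replicate 3, 6 without irradiated WT replicate 2 or with the muscle covariate, 8 without irradiated WT replicate 3 and 15 without untreated DE2 replicate 2. It was 19 without both libraries that lay apart, 20 with DESeq2, 3 with limma voom and 141 without a filter. With an estimated correlation and the muscle covariate, the neutrophil and hyperproliferative keratinocyte lists had adjusted p = 0.0907 and 0.0842, and with the hair follicle covariate 0.0237 and 0.0539. At the preset correlation that covariate ended the calls of the interferon gamma and hair follicle lists, at adjusted p = 0.308 and 0.992.

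In DE2 skin 4202 genes differed between the sites, 2180 higher and 2022 lower at the irradiated site. Krt6a (ENSMUSG00000058354, chromosome 15, 101689910 to 101694307) rose from 84 ± 61.7 to 5166 ± 843 CPM (SD, n = 3). Its log2 fold change was 5.94 ± 0.52 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 2.38e-06). The untreated DE2 libraries of this comparison had a hair follicle score of 3.02, against 8.83 in untreated WT, and a muscle share of 12.1%. Among 20 tested hyperproliferative keratinocyte genes 19 rose (19 adjusted over the list alone). Krt17 rose by 2.75 ± 0.24 and Sprr1a by 3.23 ± 0.34. The list median was 5.55 (log2), and 5.28 with members at 0 counts at their bound. The set tested higher in camera, with an adjusted p of 2.74e-19, and adjusted p = 0.0444 with an estimated correlation. The neutrophil list had 14 tested members, of which 13 rose (13 adjusted over the list alone). Stfa2 rose by 6.82 ± 0.65 and Stfa3 by 5.77 ± 0.56. The neutrophil median was 6.44 (log2), and 6.24 with members at 0 counts at their bound. Camera placed the neutrophil list higher at an adjusted p of 2.32e-11, and at adjusted p = 0.0444 with an estimated correlation. Of 31 tested hair follicle genes, 31 rose (31 adjusted over the list alone). Krtap16-1 rose by 6.58 ± 0.45 and Krt73 by 5.39 ± 0.39. The list median was 5.20 (log2), and 5.17 with members at 0 counts at their bound. The set tested higher in camera, with an adjusted p of 9.47e-55, and adjusted p = 0.0356 with an estimated correlation. Among 12 tested melanocyte genes 10 rose (10 adjusted over the list alone). Dct rose by 4.70 ± 0.30 and Mlana by 6.08 ± 0.43. The melanocyte median was 5.38 (log2), and 4.60 with members at 0 counts at their bound. Camera placed the melanocyte list higher at an adjusted p of 2.44e-18, and at adjusted p = 0.0356 with an estimated correlation. The cell cycle list had 26 tested members, of which 23 rose (26 adjusted over the list alone). Top2a rose by 2.77 ± 0.27 and Ube2c by 2.99 ± 0.25. By camera the cell cycle list was higher at an adjusted p of 2.17e-21, and had adjusted p = 0.0913 with an estimated correlation.

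Of 16 tested IL-17 and IL-36 genes, 13 rose and 1 fell (13 and 2 adjusted over the list alone). Il1b rose by 6.93 ± 0.79 and S100a9 by 6.48 ± 0.94. The list median was 4.62 (log2), and 4.02 with members at 0 counts at their bound. Camera placed the list higher at an adjusted p of 6.14e-05, and at adjusted p = 0.32 with an estimated correlation. Among 31 tested type I interferon genes 14 rose (15 adjusted over the list alone). Bst2 rose by 1.88 ± 0.30 and Isg15 by 2.79 ± 0.48. By camera the type I interferon list was higher at an adjusted p of 1.33e-04, and had adjusted p = 0.32 with an estimated correlation. The inflammatory chemokine list had 16 tested members, of which 6 rose (7 adjusted over the list alone). Ccl3 rose by 6.58 ± 0.80 and Cxcl2 by 6.91 ± 1.09. The inflammatory chemokine set tested higher in camera, with an adjusted p of 0.0123, and adjusted p = 0.345 with an estimated correlation. Of 28 tested extracellular matrix genes, 10 rose (10 adjusted over the list alone). Tnc rose by 5.59 ± 0.56 and Col6a3 by 1.97 ± 0.35. By camera the extracellular matrix list was higher at an adjusted p of 0.00377, and had adjusted p = 0.563 with an estimated correlation. Among 12 tested matrix protease genes 5 rose (5 adjusted over the list alone). Plaur rose by 5.29 ± 0.85 and Mmp13 by 4.71 ± 1.02. The matrix protease set tested higher in camera, with an adjusted p of 0.0147, and adjusted p = 0.32 with an estimated correlation. The type 2 immunity list had 14 tested members, of which 5 rose and 2 fell (5 and 2 adjusted over the list alone). Arg1 rose by 3.60 ± 0.36, Il4ra by 2.53 ± 0.26 and Il33 by 1.71 ± 0.34. Camera placed the type 2 immunity list higher at an adjusted p of 0.0477, and at adjusted p = 0.452 with an estimated correlation. That call was lost without untreated WT replicate 1 or irradiated WT replicate 2 or 3 (adjusted p = 0.062, 0.0511 and 0.0553). It was also lost without untreated DE2 replicate 2 or 3 or irradiated DE2 replicate 3 (0.127, 0.0722 and 0.0795). The list had adjusted p = 0.087 with total counts and 0.0594 without a filter. Of 18 tested macrophage genes, 3 rose (2 adjusted over the list alone). Cd14 rose by 4.87 ± 0.49 and Ms4a7 by 1.56 ± 0.53. The macrophage set tested higher in camera, with an adjusted p of 0.0164, and adjusted p = 0.563 with an estimated correlation. The macrophage call was lost without untreated DE2 replicate 2, at adjusted p = 0.0881.

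Among 23 tested skeletal muscle genes 23 fell (23 adjusted over the list alone). Myh2 was at -2.19 ± 0.44 and Neb, encoding nebulin, at -2.22 ± 0.47. Camera placed the skeletal muscle list lower at an adjusted p of 5.75e-10, and at adjusted p = 0.345 with an estimated correlation. The adipocyte list had 17 tested members, of which 11 fell (14 adjusted over the list alone). Lpl was at -1.85 ± 0.26 and Cd36 at -1.93 ± 0.27. By camera the adipocyte list was lower at an adjusted p of 9.97e-07, and had adjusted p = 0.32 with an estimated correlation. Of 15 tested circadian clock genes, 9 fell (11 adjusted over the list alone). Nr1d1 was at -1.88 ± 0.34 and Dbp at -1.63 ± 0.28. Camera placed the circadian clock list lower at an adjusted p of 1.97e-05, and at adjusted p = 0.0913 with an estimated correlation. The lists for T cells, regulatory T cells, cytotoxic cells and the interferon gamma response did not pass. Of 13 T cell genes 1 rose (1 adjusted over the list alone), while Trbc2 was at 1.17 ± 0.29 and Trbc1, which did not pass, at 1.68 ± 0.64, with a median of 1.17 and a camera adjusted p of 0.303 toward higher. The T cell list passed without a filter (adjusted p = 0.0432). Of 6 regulatory T cell genes 1 rose and 2 fell (1 and 2 adjusted over the list alone), while Areg was at 2.71 ± 0.51, Ikzf2 at -2.09 ± 0.41 and Tnfrsf4 at -1.46 ± 0.38, with a median of 0.12 and a camera adjusted p of 0.807 toward lower. Of 9 cytotoxic lymphocyte genes 2 rose (2 adjusted over the list alone), while Ccl5 and Nkg7, which did not pass, were at 2.32 ± 1.17 and 1.35 ± 0.68, with a median of 2.32 and a camera adjusted p of 0.0992 toward higher. The cytotoxic lymphocyte list passed without a filter (adjusted p = 0.05). Of 21 interferon gamma genes 2 rose (1 adjusted over the list alone), while Cd274 was at 2.67 ± 0.69 and Cxcl10 at 2.32 ± 0.79, with a median of 0.22 and a camera adjusted p of 0.807 toward higher. Klrd1 had 45 counts against 1, a ratio of 47.9 (interval 8.17 to 1934), and Gzmb 61 against 1, a ratio of 65 (11.2 to 2607). Both passed. With 0 counts at the untreated site, Krtap24-1 was at least 327-fold higher, Clec4e at least 248-fold and Cd300lf at least 175-fold. Uox, Tmprss11g and Chil4 were higher by at least 169.7-fold, 158-fold and 126-fold. With 0 counts at the irradiated site, Sbk3 was at least 33.2-fold lower, Mettl21e at least 31.3-fold and Ric3 at least 29.1-fold. Chst3 and the Mas-related receptor genes Mrgprb2 and Mrgprb3 were lower by at least 31.6-fold, 31.6-fold and 31-fold. With total counts the median of all genes moved from 0.02 to 0.26, and the higher share of calls from 51.9% of 4202 to 66.5% of 4080. The count was 788 with the muscle covariate, 1162 against a 2-fold change and 1 with the hair follicle covariate. At the preset correlation the hair follicle covariate turned the macrophage list lower, with a median of -2.57 and adjusted p = 0.00653. It ended the calls of the type I interferon, type 2 immunity, extracellular matrix and protease lists, at adjusted p = 0.875, 0.919, 0.948 and 0.382, and of the hair follicle, muscle and clock lists, at 0.769, 0.091 and 0.407. The muscle covariate ended those of the extracellular matrix and muscle lists, at adjusted p = 0.131 and 0.737. With an estimated correlation and the hair follicle covariate, the neutrophil, keratinocyte, hair follicle and melanocyte lists had adjusted p = 0.0569, 0.142, 0.758 and 0.53.

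The interaction asked whether the UVB comparison differed between the genotypes. It passed in 1585 genes, 853 with a higher and 732 with a lower UVB value in DE2. Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484) had an interaction of 3.39 ± 0.48 on the log2 scale (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 4.63e-04). Il4ra was at 2.17 ± 0.36 and Il33 at 2.09 ± 0.51. The hyperproliferative keratinocyte list had 20 tested members, of which 10 had a positive interaction (12 adjusted over the list alone). Krt6a was at 3.76 ± 0.62 and Krt17 at 2.36 ± 0.32. The list median was 2.73 (log2), and 2.86 with members at 0 counts at their bound. It was 4.19 without untreated DE2 replicate 2. Camera placed the list toward a positive interaction at an adjusted p of 1.29e-08, and at adjusted p = 0.194 with an estimated correlation. Of 14 tested neutrophil genes, 3 had a positive interaction (7 adjusted over the list alone). Stfa2 was at 4.20 ± 0.91 and Stfa3 at 2.57 ± 0.71. The neutrophil median was 2.89 (log2), and 3.85 with members at 0 counts at their bound. It was 5.86 without untreated DE2 replicate 2. The neutrophil set tested toward a positive interaction in camera, with an adjusted p of 0.00797, and adjusted p = 0.529 with an estimated correlation. The neutrophil call was lost without untreated WT replicate 3, at adjusted p = 0.0607. Among 31 tested hair follicle genes 29 had a positive interaction (31 adjusted over the list alone). Krtap16-1 was at 6.08 ± 0.54 and Krt73 at 4.98 ± 0.48. The hair follicle median was 4.75 (log2), and 4.72 with members at 0 counts at their bound. Camera placed the hair follicle list toward a positive interaction at an adjusted p of 2.75e-58, and at adjusted p = 0.0287 with an estimated correlation. The melanocyte list had 12 tested members, of which 10 had a positive interaction (10 adjusted over the list alone). Dct was at 4.61 ± 0.38 and Mlana at 6.04 ± 0.52. The melanocyte median was 5.17 (log2), and 4.55 with members at 0 counts at their bound. By camera the melanocyte list went toward a positive interaction at an adjusted p of 6.05e-22, and had adjusted p = 0.0191 with an estimated correlation. Of 26 tested cell cycle genes, 18 had a positive interaction (24 adjusted over the list alone). Top2a was at 2.78 ± 0.35 and Ube2c at 3.00 ± 0.33. Camera placed the cell cycle list toward a positive interaction at an adjusted p of 3.82e-25, and at adjusted p = 0.0691 with an estimated correlation.

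Among 28 tested extracellular matrix genes 4 had a positive interaction (5 adjusted over the list alone). Tnc was at 5.69 ± 0.71 and Col6a3 at 1.92 ± 0.49. By camera the extracellular matrix list went toward a positive interaction at an adjusted p of 0.0141, and had adjusted p = 0.706 with an estimated correlation. The extracellular matrix call was lost without irradiated WT replicate 3, untreated DE2 replicate 2 or irradiated DE2 replicate 2, at adjusted p = 0.069, 0.0581 and 0.0984. The matrix protease list had 12 tested members, of which 1 had a positive interaction (6 adjusted over the list alone). Mmp13 was at 5.82 ± 1.60 and Plaur, which did not pass, at 4.13 ± 1.27. The matrix protease set tested toward a positive interaction in camera, with an adjusted p of 0.0339, and adjusted p = 0.523 with an estimated correlation. The matrix protease call was lost without untreated WT replicate 3, irradiated WT replicate 3 or irradiated DE2 replicate 2, at adjusted p = 0.0607, 0.069 and 0.0816. Of 23 tested skeletal muscle genes, 8 had a negative interaction (23 adjusted over the list alone). Myh2 was at -2.58 ± 0.61 and Eno3 at -2.24 ± 0.62. By camera the skeletal muscle list went toward a negative interaction at an adjusted p of 1.77e-09, and had adjusted p = 0.529 with an estimated correlation. Among 17 tested adipocyte genes 5 had a negative interaction (7 adjusted over the list alone). Lpl was at -1.70 ± 0.37 and Pnpla2 at -1.79 ± 0.36. The adipocyte set tested toward a negative interaction in camera, with an adjusted p of 4.77e-04, and adjusted p = 0.594 with an estimated correlation. The circadian clock list had 15 tested members, of which 4 had a negative interaction (8 adjusted over the list alone). Nr1d1 was at -1.83 ± 0.48 and Dbp at -1.89 ± 0.39. Camera placed the circadian clock list toward a negative interaction at an adjusted p of 1.66e-04, and at adjusted p = 0.194 with an estimated correlation. The lists for interferons, T cells, regulatory T cells, cytotoxic cells, type 2 immunity and the IL-17 and IL-36 axis did not pass. Of 31 type I interferon genes 0 passed (0 adjusted over the list alone), while Oas1g was at 2.84 ± 1.12 and Trim30a at 1.34 ± 0.57, with a median of 0.40 and a camera adjusted p of 0.372 toward positive. Of 21 interferon gamma genes 1 had a negative interaction, and 0 passed adjusted over the list alone, while Iigp1 was at -3.18 ± 0.95 and Gbp6, which did not pass, at -3.25 ± 1.58, with a median of -0.25 and a camera adjusted p of 0.541 toward negative. Of 13 T cell genes 0 passed (0 adjusted over the list alone), while Trbc2 was at 1.23 ± 0.42 and Cd27 at -2.28 ± 1.04, with a median of 1.07 and a camera adjusted p of 0.264 toward positive. Of 6 regulatory T cell genes 0 passed (0 adjusted over the list alone), while Areg was at 1.94 ± 0.68 and Ikzf2 at -1.27 ± 0.57, with a median of -0.27 and a camera adjusted p of 0.998 toward positive. Of 9 cytotoxic lymphocyte genes 0 passed, and 2 had a positive interaction adjusted over the list alone, while Nkg7 was at 3.07 ± 1.02 and Ctsw at 1.83 ± 1.14, with a median of 2.66 (1.83 with bounds for members at 0 counts) and a camera adjusted p of 0.13 toward positive. The cytotoxic lymphocyte list passed without untreated WT replicate 2 (adjusted p = 0.0269). Of 14 type 2 immunity genes 3 had a positive interaction (4 adjusted over the list alone), while Arg1 was at 3.39 ± 0.48 and Il4ra at 2.17 ± 0.36, with a median of 0.91 and a camera adjusted p of 0.078 toward positive. This list passed without irradiated WT replicate 2 (adjusted p = 0.0314), untreated DE2 replicate 1 (0.026), both (0.0147) or irradiated DE2 replicate 1 (0.0298). Of 16 IL-17 and IL-36 genes 1 had a negative interaction (1 adjusted over the list alone), while S100a8 and Il1f6, which did not pass, were at 3.50 ± 1.19 and 2.17 ± 0.78, with a median of 2.27 (2.41 with bounds for members at 0 counts) and a camera adjusted p of 0.0931 toward positive. This list passed without untreated WT replicate 2 (adjusted p = 0.0071), irradiated WT replicate 2 (0.0255) or untreated DE2 replicate 2 (6.36e-04).

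The largest positive interactions were in genes with 0 counts in untreated DE2, for which fitted values are no bound. Counts in untreated WT, irradiated WT and irradiated DE2 were 1930, 1996 and 921 for Krtap24-1, 475, 303 and 309 for Krtap5-3, and 815, 816 and 307 for Tyr. They were 38, 14 and 312 for Csf3r, 19, 16 and 446 for Tmprss11g, and 124, 150 and 478 for Uox. Among the most negative, Fgf9, Chst3 and Tnni3k had 59, 101 and 136 counts in untreated DE2 and 7, 0 and 6 in irradiated DE2. Vwa7, Ppp2r2c and Mrgprb2 had 101, 180 and 101, against 1, 1 and 0. With total counts the median of all genes moved from 0.04 to 0.38, and the higher share of calls from 53.8% of 1585 to 76.8% of 1588. The count was 328 with the muscle covariate, 419 against a 2-fold change, 1 with the hair follicle covariate and 2438 without a filter. Without untreated WT replicate 1, 2 or 3 it was 1017, 878 or 1021, and without irradiated WT replicate 2 it was 982. Without untreated DE2 replicate 1, 2 or 3 it was 2585, 971 or 950, and without irradiated DE2 replicate 1 or 2 it was 986 or 938. At the preset correlation the hair follicle covariate ended the calls of the extracellular matrix, protease and hair follicle lists, at adjusted p = 0.846, 0.365 and 0.631. It also ended those of the adipocyte, muscle and clock lists, at 0.149, 0.177 and 0.371. The muscle covariate ended those of the extracellular matrix and muscle lists, at adjusted p = 0.208 and 0.891. With an estimated correlation and the hair follicle covariate, the hair follicle and melanocyte lists had adjusted p = 0.727 and 0.445.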

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

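The tests of dilution by muscle, of normalization, of exchanged libraries, of the genotype difference without UVB, and of hair follicle and muscle content with libraries left out were chosen only after the result was seen. The others in this part had their tests and bounds set down before. For 3 of those, the absence of whole follicles, hair follicle content and muscle content, the conditions beyond the bound were changed after the values were seen. Under the first version, the bound alone, all 3 were excluded. The condition now used asks that the bound be passed by more than the interquartile range. For muscle and hair follicle content passing it by any amount is enough where the directions with libraries left out also exclude the explanation. For the absence of whole follicles 3 versions were tried, of which 1, that no member be lower, left it open because Lgr5 and Lhx2 were lower. For hair follicle content each later version left it open. For muscle content 5 versions were tried, of which 1, the bound with the interquartile range alone, left it open. Another, on the range of muscle scores, was dropped because 1 library set that range. The results here were picked because the UVB comparison differed between the genotypes by the interaction test. No test for a single library far from the rest was made in groups of 3. Irradiated WT replicate 2 and untreated DE2 replicate 1 were picked without such a test, after the data were seen. The look at splits that keep the untreated groups was also chosen after their counts were seen.

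At the untreated site the hair follicle list was lower in DE2 by a median of -6.02 on the log2 scale. Dilution by muscle would lower other compartments about as far, but the epidermal differentiation list had a median of 0.17 with an interquartile range of 1.23, and under total-count scaling the hair follicle median was -6.37, which argues against dilution and normalization. An exchange of single libraries would leave a low library elsewhere, and 0 of the 9 other libraries had a score at or below the highest untreated DE2 score of 3.86, though a wrong origin of the whole group is not excluded by this. A follicle stem cell list, fixed beforehand, had a median of 0.77, above the bound of -1 by more than its interquartile range. Col17a1 was higher by 0.97, 5 members did not pass (0.64 to 2.34), and Lgr5 and Lhx2 were lower by 1.97 and 1.80. That meets the condition now used against an absence of whole follicles. Whether the members mark follicles alone was not tested, so absence and partial loss stay open. A candidate explanation, untested, is a resting stage of the hair cycle in untreated DE2 skin and a growing stage at the other sites, and genotype, age, shaving and body position are confounded with it in this design.

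The neutrophil list was higher in irradiated DE2 than irradiated WT skin by a median of 4.01 (interquartile range 2.27), and with the muscle score as a covariate the median was 4.10 (interquartile range 2.69), 9 of 14 members passed and the list had adjusted p = 0.0279 with an estimated correlation, though the median lay above the bound of 2 by less than its range. With 1 library left out, the muscle list went from -0.67 (without irradiated WT replicate 3, adjusted p = 2.11e-04) to 0.51 (without irradiated WT replicate 2, adjusted p = 2.46e-04), not passing in the other 10 fits, while the neutrophil list stayed higher at 3.73 to 5.86 and passed in each of the 12 fits, which argues against muscle content as the whole cause. With the hair follicle score as a covariate the median was 2.42 (interquartile range 3.15) and 0 of 14 members passed. The neutrophil list then had a camera adjusted p of 4.16e-06, and 0.128 with an estimated correlation. The hair follicle list stayed lower, at -0.94 or below with 1 library left out. Its score was 8.23 ± 0.48 in irradiated DE2 and 9.39 ± 0.25 in irradiated WT (SD, n = 3). Over all 4 groups 97.2% of that score's variance lies between groups, a share not computed for the irradiated groups alone. Hair follicle content and group thus cannot be told apart here. A genotype difference already present without UVB would leave little interaction, and the median interaction was 2.89 (interquartile range 3.78), 3.85 with members at 0 counts set at their bound and 2.91 to 5.86 with 1 library left out (highest without untreated DE2 replicate 2), with camera adjusted p = 0.00797, 0.0607 without untreated WT replicate 3 and adjusted p = 0.529 with an estimated correlation, so that a share present without UVB cannot be told apart. A response to UVB that differs with the Foxp3 genotype remains a hypothesis.

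Few genes passed for UVB in WT skin, where irradiated replicate 2 had 7.84% of its counts in the muscle list. Leaving that library out gave 6 calls and a muscle covariate gave 6, between the values set beforehand for and against each explanation (over 30, and at most 4), so neither could be decided. The simulated comparison recovered 58% of 4-fold and 28% of 2-fold changes with 3 libraries a group, among genes with a mean log2 CPM of at least 1.

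For the 4 comparisons of 3 against 3 libraries, the 10 splits cannot give a share under 0.1. The real split called 3 genes for UVB in WT (1 split as large, itself; highest other 1), 4202 for UVB in DE2 (1; highest other 0), 448 for genotype with UVB (1; highest other 0) and 3477 for genotype without UVB (1; highest other 0). For gene lists the real counts were 10, 15, 19 and 10 in the same order, with 5, 4, 1 and 8 of the 10 splits as large and highest other counts of 15, 19, 17 and 17. For the interaction, 3 of 100 splits drawn, the real one included, called at least 1585 genes (highest other 2506). The count followed the untreated libraries, with 473 to 2506 calls in the 11 splits that kept their 2 groups and 0 to 12 in the other 89. All 3 splits were among these 11, so the share, though under 0.05, speaks of the untreated grouping and does not test the interaction itself. In 67 of the 100 splits at least 10 lists passed the interaction test, with up to 25, so chance is not excluded for the number of lists.

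Lists whose UVB comparison differed between genotypes had median interactions of 4.75 (hair follicle), 5.17 (melanocyte), 2.62 (cell cycle), 2.73 (hyperproliferative keratinocyte), 2.89 (neutrophil), 0.67 (extracellular matrix), 1.49 (proteases), -0.98 (adipocyte), -1.01 (circadian clock) and -2.24 (skeletal muscle). The neutrophil and keratinocyte medians were 5.86 and 4.19 without untreated DE2 replicate 2. The extracellular matrix median was 1.03 without untreated DE2 replicate 1, 1.06 without irradiated DE2 replicate 1 and 0.41 without irradiated DE2 replicate 2. The protease median was 2.26 without untreated WT replicate 2, 2.25 without irradiated WT replicate 2, 2.96 without untreated DE2 replicate 1, 2.45 without irradiated DE2 replicate 1 and 0.97 without irradiated DE2 replicate 2. The adipocyte median was -0.62 without untreated WT replicate 2, -1.49 without untreated DE2 replicate 2 and -0.18 without untreated DE2 replicate 3. The muscle median was -1.31 without irradiated WT replicate 2. The others moved by less than 1.5 times with 1 library left out. Single genes with a positive interaction were Klk6 (3.55), Rbp2 (2.45), Krt6a (3.76), Krt16 (2.92), Krt17 (2.36), Sprr1a (2.48), Lce3c (2.21), Hbegf (2.80), Ier3 (2.07), Arg1 (3.39), Il4ra (2.17), Il33 (2.09), Cd14 (2.97), Stfa2 (4.20), Stfa3 (2.57), Csf3r (10.90), Tnc (5.69), Col6a3 (1.92), Mmp13 (5.82), Krt73 (4.98), Krt86 (5.10), Krtap16-1 (6.08), Krtap24-1 (11.01), Krtap5-3 (10.02), Lef1 (5.26), Dlx4 (8.69), Dct (4.61), Mlana (6.04), Tyr (9.46), Oca2 (9.13), Top2a (2.78), Ube2c (3.00), Krtap3-2 (2.53), Sptssb (8.84), Tmprss11g (10.23) and Uox (9.84). A negative one was seen for Iigp1 (-3.18), Skint5 (-4.43), Myh2 (-2.58), Tnni3k (-6.81), Lpl (-1.70), Cd36 (-1.68), Pnpla2 (-1.79), Nr1d1 (-1.83), Dbp (-1.89), Eno3 (-2.24), Neb (-2.29), Chst3 (-9.10), Col4a6 (-4.98), Dab1 (-5.66), Fgf9 (-9.76), Mrgprb2 (-5.83), Ppp2r2c (-5.85) and Vwa7 (-6.68). Klk6 and Rbp2 had also passed for UVB in WT skin. These are fitted values on the log2 scale, and those of genes with a group at 0 counts depend on the prior count and are no bound.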

How the results depend on the processing

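Leaving out irradiated WT replicate 2 and untreated DE2 replicate 1 together, the doubted libraries, was chosen after seeing the data. The other alternatives were fixed before. No paired analysis was possible because the labels tie no library to an animal. RLE scaling and the stricter filter kept every count of genes within 1.5 times. In the order UVB in WT, UVB in DE2, genotype with UVB, genotype without UVB and interaction, the counts of genes were 3, 4202, 448, 3477 and 1585. Leaving out 1 library at a time gave 0 to 15, 2979 to 4622, 130 to 616, 2108 to 3881 and 878 to 2585. A test against a 2-fold change gave 0, 1162, 49, 777 and 419, and the hair follicle covariate 0, 1, 87, 0 and 1. The muscle covariate gave 6, 788, 454 and 328 outside the genotype comparison with UVB. Without a filter there were 141, 1031 and 2438 for UVB in WT, genotype with UVB and the interaction. For UVB in WT, total counts gave 1, only the WT libraries 0, DESeq2 20 and both doubted libraries left out 19. For genotype with UVB, DESeq2 gave 853, limma voom 806 and both left out 754. The causes were not tested, beyond the stricter hypothesis of the 2-fold test and the overlap of the covariates with the groups (97.2% and 68.9% of their variance lies between groups).

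The counts of lists were 10, 15, 19, 10 and 10. They were 2, 4, 10, 2 and 2 with an estimated correlation, and 9 to 12, 13 to 16, 18 to 21, 8 to 14 and 8 to 13 with 1 library left out. The fry test called 0 for UVB in WT. For genotype without UVB, 16 lists passed without a filter and 6 without both doubted libraries. Of the lists that passed, the fry test did not call 10, 0, 6, 3 and 3. With a library left out, 9, 2, 5, 5 and 4 lists that had not passed did so in at least 1 of the 12 fits.

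Of the named genes, 0 of 3, 44 of 52, 21 of 48, 27 of 38 and 23 of 35 that passed did so in every fit with a library left out, and TMM, RLE and total-count scaling gave them the same sign. The hair follicle covariate turned the log2 fold change for UVB in DE2 of Lpl (0.38), Myh2 (0.64), Dbp (0.80), Sbk3 (2.82), Ccl5 (-2.28), Neb (1.57) and Nkg7 (-2.24). There the muscle covariate turned Ccl5 (-0.60). For genotype without UVB the hair follicle covariate turned Cyp1a1 (-1.36), Tnni3k (-5.60), Pgf (-0.76), Myh2 (-0.0532), Lpl (-1.01), Nr1d1 (-0.17), Dbp (-1.13), Il1b (-0.27), Areg (0.88), Arg1 (1.64) and S100a9 (-7.62). For the interaction it turned Tnni3k (0.76), Lpl (0.30), Areg (-0.11), Oas1g (-0.12), Nkg7 (-0.10), Dbp (0.30), Eno3 (0.21) and Trim30a (-1.20). Ikzf2, which did not pass for genotype with UVB, ranged from -0.84 to 0.13 with 1 library left out, the latter without irradiated WT replicate 2, and was at 0.13 without both doubted libraries. S100a9, which did not pass for genotype without UVB, ranged from -0.33 without untreated DE2 replicate 2 to 2.93 without untreated WT replicate 3, and was at -0.0873 with the muscle covariate. At totals of 2809142 to 4741726 counts, a group floor of 3 counts hides genes such as Foxp3.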

Other observations

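The comparison of the 100 genes below was chosen after the data were examined. The list tests were fixed before. The UVB comparisons in WT and DE2 share no library but share each gene's fitted spread. The 100 genes with the smallest p for UVB in WT are thus no independent check in DE2. Of these, 88 moved the same way in DE2 and 70 passed there in that direction, while 27.8% of all 15126 genes passed in DE2 in either direction. Across all genes the log2 fold changes of the 2 comparisons had a Pearson r of 0.23 and a Spearman rho of 0.14, and genes are not independent replicates. The 3 genes that passed in WT, Klk6, Rbp2 and Flg, passed in the same direction in DE2.

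The list of p53 targets and DNA damage genes, which respond to ultraviolet light, passed in none of the 5 comparisons (camera adjusted p = 0.945 for UVB in WT and 0.975 in DE2), although 6 of its 27 members rose and 3 fell in DE2. The oxidative stress list had 6 of 16 members higher and 3 lower for UVB in DE2, and the epidermal differentiation list 17 higher and 11 lower of 40, with neither passing the list test (camera adjusted p = 0.0992 and 0.115). The time between the last UVB dose and sampling is not given in the sources used here. The lists for sebaceous gland, mast cells, MHC class II presentation, dendritic and Langerhans cells and B and plasma cells did not pass with all libraries in any of the 5 comparisons, with lowest camera adjusted p-values of 0.115, 0.127, 0.0745, 0.317 and 0.131. With 1 library left out, the mast cell list passed for genotype with UVB in 8 of 12 fits, with medians of 1.04 to 1.55 and a highest adjusted p of 0.0873. The MHC class II list passed in 3 of 12 for genotype without UVB and 2 of 12 for UVB in WT, and the sebaceous gland list in 1 of 12 for UVB in WT. Without a filter the mast cell list passed for genotype with UVB and UVB in DE2 (adjusted p = 0.00238 and 0.0496), B and plasma cells for genotype with UVB (0.0145), sebaceous gland for UVB in WT (0.0237) and MHC class II for genotype without UVB (0.0145). With only the libraries compared, mast cells passed for genotype with UVB (0.0139) and MHC class II for UVB in WT (0.0108). For UVB in DE2 the oxidative stress list passed without a filter (0.0486), and the epidermal differentiation list with only the DE2 libraries (0.00376) and without untreated or irradiated WT replicate 3 (0.0419 and 0.0346).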
